A study of Mus musculus with 7 samples.

How the data were processed

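The values are the authors' deposited counts, raw UMIs per gene and cell. The values themselves are whole numbers with freely differing cell totals, and no normalization was found in them. Per the submitters' processing notes, CASAVA 1.8, Cell Ranger 2.0.1 and Seurat 2.2 were used with build mm10, without roles. The rule by which the authors chose cells, the annotation release and the treatment of the retroviral sequences are not given in the sources used here. The time course lies in 1 table, and its cells were assigned to libraries by the number that ends each barcode, per the labels. The 5p library lies in its own table, and per the labels a Chromium 3′ v2 kit and a V(D)J kit were used. Which kit made it is not given in the sources used here, and only its title carries "5p".

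The labels give Thy1-positive, GFP-negative sorting before infection, culture with or without the inhibitors and harvest as GFP-positive or dsRed-positive cells. They give both inhibitors for every GMT library and neither virus nor inhibitors for day -1. What dsRed marks, and what "pos" stands for, is not given in the sources used here. The protocol speaks of 3 biological replicates per condition, and 1 library per group was analysed here.

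Gene IDs of the tables (38293) were matched to GENCODE vM21 on mm10, which gave 36345 a symbol and left 0.213% of UMIs on IDs without one. Coordinates, gene types and exon overlaps come from that annotation. Of the list symbols, 3 were matched through synonyms (Ctgf to Ccn2, Cyr61 to Ccn1, Wisp1 to Ccn4).

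Counts were summed over every deposited cell of a library and divided by the library's total to give CPM. Differences are log2 of CPM plus 10 over CPM plus 10, and the size rule asks for a 2-fold difference on that scale among genes with at least 100 UMIs over the 2 libraries. Printed folds are ratios of CPM without that addition, with an exact conditional binomial interval on the 2 counts. CPM intervals are exact Poisson and shares have exact binomial (Clopper-Pearson) intervals, all at 95% and for counting error only. A count of 0 was limited by 3 counts of the total. No test was made.

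The named genes follow a rule fixed before the data were examined. At days 1 and 14 against day -1 they are Gata4, Mef2c and Tbx5, the 8 largest and 8 smallest log2 differences, and the 3 members of each list with the highest mean CPM. At the other days and between consecutive times they are the 5 largest and 5 smallest. Mitochondrially encoded genes, ribosomal protein genes and unnamed gene models were left out of the ranking. Other members of lists are named because they passed the size rule, and genes leading clusters were chosen after their values were seen. Some items are not reported here.

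The 28 gene lists cover sarcomere, calcium handling, cardiac transcription factors, the reprogramming factors, atrial, ventricular, skeletal muscle, mitochondrial energy, glycolysis, extracellular matrix, fibroblast identity, TGF-beta response, Wnt targets, S phase, G2M phase, interferon, inflammatory, p53, integrated stress response, immediate early, adipocyte, bone, macrophage, endothelial, epicardial, pericyte, Schwann and erythroid genes. Each median was placed as a percentile among 10000 random lists matched in 10 bins of expression. Counts of a list are over its measured members, those with at least 100 UMIs over the 2 libraries compared. Genes of a list are not independent.

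Shares of cells with a UMI were computed after drawing 3000 UMIs without replacement from each cell (seed 1), and cells with fewer were left out. Cells with and without a factor UMI were compared at the same depth, by summed counts of a list.

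For clustering, the 6 libraries were joined without batch correction, since batch and time are the same here. Genes in at least 10 cells were normalized to 10000 counts per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.8 with 5 iterations were used. A cluster was named when 4 markers of a type were 2-fold above other cells and a marker stood among its 10 leading genes by fold. Marker lists were fixed before the data were examined and these thresholds after the clusters were seen. Of 23 clusters 9 had no name. Phase scores used 50 control genes per list, and a score above 0 called a phase.

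Doublets were scored by Scrublet within each library with exact neighbours and automatic thresholds. It called 224 cells (0.729%), 3, 63, 108, 5, 40 and 5 along the time course, and the numbers depend on those thresholds and on the neighbour search. Doublets were left in the main results. Free RNA was not removed.

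As a self-test, counts were simulated from the depths of day 1 and day 14 against day -1, with 50 genes at each of 4 folds. The rule recovered 36 and 54% of genes simulated at 3-fold, 66 and 62% at 4-fold and 86 and 80% at 8-fold. It recovered 0% at 1.5-fold, which lies below its 2-fold threshold and so could hardly be called. Of genes simulated without a difference, 0 of 12220 and 0 of 12118 were called. The 10 CPM added hides differences of genes of low level, and simulated counts carry no variation between cultures.

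Before the data were examined 42 alternatives were fixed: a pseudocount of 1 CPM, 2 other scalings, the mean of cell CPM, UMI minima of 1000 and 1, a cell filter of 1000 genes and 10% mitochondrial UMIs, exclusion of called doublets, thinning to 1500 UMIs or none, at least 2 UMIs, Leiden resolutions 0.4 and 1.2, 15 principal components, clustering without phase genes, a score threshold of 0.1, and other definitions of a factor cell. After the data were seen 9 were added, namely the exclusion of macrophage-like, endothelial-like and Schwann-like cells, the exclusion of the 5% of cells with the highest doublet scores, and clustering without cell type markers.

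Versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.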

Results

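Single-cell RNA sequencing followed mouse cardiac fibroblasts during direct reprogramming toward a cardiomyocyte-like state. The cells came from explants of neonatal mouse hearts carrying a GFP reporter under the alpha-myosin heavy chain (Myh6) promoter. Per the labels' protocols, Thy1-positive, GFP-negative cells were sorted and infected with retroviruses for Gata4, Mef2c and Tbx5 (GMT), transcription factors of heart development. All infected cultures also received sb431542, an inhibitor of TGF-beta receptor signalling, and xav939, an inhibitor of Wnt signalling. The time course held 6 libraries, 1 each from uninfected cells at day -1 and from GMT cells at days 1, 2, 3, 7 and 14, with 4098, 3633, 9018, 7362, 4294 and 2324 cells in that order. A further day 1 library carries "5p" in its title and held 2899 cells. The day 14 library is labelled "pos", which the labels do not explain.

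Total depth was 4.96e7 UMIs (unique molecular identifiers, each counting 1 captured transcript) at day -1, 4.72e7 at day 1, 1.12e8 at day 2, 8.89e7 at day 3, 4.84e7 at day 7, 2.49e7 at day 14 and 5.13e7 in the 5p library. Median UMIs per cell were 12533, 12781, 11654, 10516, 10068.5 and 10133.5 along the time course and 18253 in the 5p library. Ribosomal protein genes took 20.9, 22.0, 21.9, 22.5, 14.4 and 12.4% of UMIs along the time course, and mitochondrially encoded genes took 3.26, 3.75, 4.71, 4.63, 6.20 and 4.98%. With 1 library per group no difference has a replicate check, and no test was made. Intervals are 95% and cover counting error only. Day -1 cells had no virus and no inhibitors, and the protocol harvests infected cells by FACS for GFP or dsRed, so infection, inhibitors, time in culture and sort differ together from day -1.

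The delivered factors were read first. Mef2c (ENSMUSG00000005583, chromosome 13, 83504034 to 83667080, mm10) stood at 5.08 CPM (UMIs scaled to the total of the library, Poisson interval 4.47 to 5.75) at day -1. Its level was 449 CPM (443 to 455) at day 1, 371 (368 to 375) at day 2, 218 (215 to 221) at day 3, 288 (283 to 293) at day 7 and 998 (985 to 1010.3) at day 14. Tbx5 (ENSMUSG00000018263, chromosome 5, 119832668 to 119885219) stood at 0.383 CPM (0.231 to 0.598) at day -1, at 5.08 to 6.50 CPM from day 1 to day 7 and at 19.2 CPM (17.5 to 21.0) at day 14. Gata4 (ENSMUSG00000021944, chromosome 14, 63198922 to 63271692) was slightly lower at day 1 than at day -1, at 24.6 CPM (23.2 to 26.1) against 28.1 (26.6 to 29.6), and reached 71.5 CPM (68.2 to 74.9) at day 14. With median-of-ratios scaling its day 1 level was 27.4 CPM, inside that day -1 interval, so the small day 1 difference depends on scaling. A 3′ library may not read a retroviral transcript whose 3′ end is not in the reference, and viral and endogenous transcripts were not told apart.

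After each cell was thinned to 3000 UMIs, Mef2c was detected in 1.83% of cells at day -1 (exact binomial interval 1.44 to 2.29), 38.1% at day 1 (36.5 to 39.7), 39.5% at day 2, 29.5% at day 3, 34.6% at day 7 and 75.2% at day 14 (73.4 to 77.0). Unthinned shares of Mef2c were 5.61, 50.9, 57.1, 46.8, 51.8 and 85.6%. Thinning left out 108 cells at day -1, 2 at day 1 and 59 at day 14. Macrophage-like cells, a type that transcribes Mef2c itself, gave 6.95% at day -1 and 14.1 to 17.1% in the GMT libraries. Gata4 was detected after thinning in 8.45% of cells at day -1 and 18.0% at day 14, against 1.66 and 0.901% of macrophage-like cells. Tbx5 was detected in 0.150% and 5.39%, against 0 of 302 and 0 of 111 macrophage-like cells, which allow shares of up to 0.993 and 2.70%. Median UMIs before thinning were 12734, 12786, 11654, 10516, 10068.5 and 10251 for the cells used and 5856, 5626.5, 7648, 8711, 8027 and 9851 for macrophage-like cells.

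One day after infection, some genes of the cardiac contractile apparatus and of mitosis were at least 2-fold higher than in uninfected cells, and several inflammatory genes were lower. Tnnt2, the cardiac troponin T of the thin filament (ENSMUSG00000026414, chromosome 1, 135836354 to 135852260), stood at 390.2 CPM (385 to 396) against 19.6 (18.4 to 20.9), 19.9-fold higher (18.7 to 21.3). Myl4, the atrial myosin light chain (ENSMUSG00000061086, chromosome 11, 104550663 to 104595753), was 23.7-fold higher (21.2 to 26.6), at 149.5 against 6.31 CPM. Mef2c was 88.5-fold higher (78.1 to 101) and Tbx5 13.3-fold (8.31 to 22.4), of which only Mef2c passed 2-fold with 10 CPM added (log2 4.93 and 0.54), and Cnn1, the calponin of contractile cells, 17.9-fold (16.2 to 19.7). Of the 12418 genes compared, 201 were at least 2-fold higher and 154 at least 2-fold lower at day 1, on a log2 scale with 10 CPM added. The higher genes made up 56.6% of these, 74.6% with median-of-ratios scaling and 48.4% with 1 CPM added.

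The other largest differences at day 1 were Cenpa, a centromeric histone (116 against 3.89 CPM), S100a4, a calcium-binding protein of motile mesenchymal cells (575 against 56.6), Map3k7cl (88.1 against 2.24) and Ube2c, a ubiquitin-conjugating enzyme of mitotic exit (149.8 against 10.1). The smallest were Serpinb2, a plasminogen activator inhibitor (28.7-fold lower, 24.7 to 33.6), the neutrophil chemokine Cxcl1 (10.0-fold lower), Ptgs2, the inducible cyclooxygenase (10.6-fold lower), Pmepa1, a TGF-beta-induced regulator (6.20-fold lower), tissue factor F3 (5.72-fold lower) and Ifrd1 (6.41-fold lower). Sprr1a and Sprr2h, small proline-rich proteins of the cornified envelope, were 8.92-fold and 65.2-fold lower. Exons of Serpinb2 and S100a4 overlap another gene on the same strand, so these counts are uncertain. Those of Myl4, Ube2c and Ifrd1 overlap a gene on the opposite strand, which matters only if reads were counted without regard to strand.

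By gene list, 8 of 18 measured cardiac sarcomere genes were at least 2-fold higher at day 1 and none lower, with a median log2 difference of 0.61 (percentile 100 among 10000 random lists matched on expression). The higher members numbered 14 with 1 CPM added and 5 among genes with at least 1000 UMIs. Besides Tnnt2 and Myl4 the 8 genes held Cryab, a small heat-shock protein of the sarcomere (2.94-fold), whereas the tropomyosin Tpm1 stood at 2614 against 2950.3 CPM. None of the 7 measured calcium handling genes was past 2-fold (3 were higher with 1 CPM added), and the calcium pump Atp2a2 stood at 111 against 104 CPM. Of the cardiac transcription factor and natriuretic peptide list, Nppa was higher (17.8 against 0.0605 CPM, 3 UMIs at day -1, ratio 294, counting interval 100.3 to 1429), Ankrd1, a muscle stress-response cofactor, was lower (1024 against 2553 CPM) and 5 of 7 were neither. The atrial list had 3 of 8 measured members higher (10 listed), and the ventricular list 1 of 3 measured (8 listed), Lbh (3.04-fold). The G2M phase list had 19 of 52 members higher and none lower (median 0.66, percentile 100), and 37 higher with 1 CPM added. Its cyclin-dependent kinase subunit Cks1b stood at 239 against 114 CPM. The S phase list had 2 of 42 higher (median 0.19).

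Fibroblast programmes differed in both directions at day 1. Acta2, the smooth muscle actin of contractile fibroblasts (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590), stood at 11906 CPM (11875 to 11937) against 6276 (6254 to 6298), and transgelin Tagln was 1.87-fold higher (1.86 to 1.88). Cells named myofibroblast or smooth muscle-like made up 6.44% of cells against 0.342%. At day -1, however, 71.7% of cells lay in an unnamed cluster nearly all from that library, so contractile cells there may carry no name. In the TGF-beta response list 4 of 22 members were at least 2-fold higher (Cnn1, Myl9, Tpm2, Actg2, all contractile proteins) and 4 lower, among them the secreted matricellular proteins Ccn1 and Ccn2 and the Smad inhibitor Skil. The extracellular matrix list had 1 of 29 higher and 5 lower (Col1a1, Col3a1, Dcn, Fbln1, Lox), with a median of -0.23 at percentile 1.99. Fibroblast identity genes were higher in 3 of 17 (Thy1, S100a4, Prrx1), and the intermediate filament Vim was 1.81-fold higher. Among Wnt targets the cyclin Ccnd1 was 4.33-fold higher and Ccn4 2.30-fold lower, of 6 measured.

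Stress and immune lists at day 1 had most members past 2-fold in neither direction. Inflammatory cytokine and acute phase genes were lower in 4 of 16 (Cxcl1, Cxcl2, Ptgs2, Mmp3) and higher in 1, the monocyte chemokine Ccl7 (265 against 98.3 CPM), with a median of -0.53 at percentile 0. In the integrated stress response list 2 of 12 were lower, Trib3 and the regulator Atf4 (133 against 410.0 CPM), and none higher. The p53 list had 2 of 12 higher (Gdf15, Btg2), the immediate early list 1 of 13 higher (Dusp1, 3.09-fold) and 1 lower (Hspa1a), and the interferon list none of 16. None of 21 mitochondrial energy genes and none of 17 glycolysis genes passed 2-fold. Markers of other cell types were also read: 5 of 12 macrophage markers were higher (Tyrobp 210.0 against 85.5 CPM), 1 of 10 epicardial markers was higher (Krt19), 1 of 6 pericyte and smooth muscle markers was lower (Ndufa4l2), and none of the 3 endothelial, 2 skeletal muscle, 6 adipocyte and 4 bone and cartilage genes measured passed 2-fold. The Schwann and erythroid lists had 0 measured members, and Hbb-bs had 0 UMIs in both libraries.

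From day 2 to day 7, Myl4 and Tnnt2 headed the differences from day -1 in each library. Myl4 stood at 817, 2187 and 2114 CPM at days 2, 3 and 7 and Tnnt2 at 1127, 2365 and 3699 CPM. Myl7, the second atrial light chain (ENSMUSG00000020469, chromosome 11, 5896637 to 5898782), stood at 519.7 CPM at day 3 and 1227 at day 7 against 1.39 at day -1, which is 374-fold (295 to 480.3) and 882-fold (697 to 1134) higher. Nppa, atrial natriuretic peptide, stood at 259.7 and 941 CPM, and its ratios to the 3 UMIs at day -1 were 4295 (1469.6 to 20830.3) and 15561 (5324 to 75458). At day 7 the cardiac actin Actc1 stood at 276 CPM against 4 UMIs (0.0806 CPM) at day -1. Mef2c and S100a4 were also among the largest at day 2, and Nid2, a basement membrane nidogen, at days 2 and 3 (265 and 308 against 2.66 CPM).

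The smallest differences at days 2, 3 and 7 included Lce1g and Crct1, genes of the epidermal differentiation complex, and Serpinb2. Lce1g was 23.7-fold lower at day 2, 27.3-fold at day 3 and 28.2-fold at day 7, and Crct1 15.8-fold, 10.5-fold and 15.1-fold. F3 was 10.9-fold lower at day 2 and 9.13-fold at day 3, Ptgs2 12.7-fold at day 3 and 35.1-fold at day 7, Ifrd1 9.63-fold at day 2, and Lox, the collagen cross-linking lysyl oxidase, 14.5-fold at day 7 (47.7 against 692 CPM). Genes at least 2-fold higher and lower numbered 402 and 273 of 13556 at day 2, 399 and 379 of 13288 at day 3, and 733 and 415 of 12811 at day 7. With 1 CPM added in place of 10 they numbered 1337 and 774, 1262 and 1039, and 1868 and 1067. The Nid2, Nppa, Ifrd1 and Lox exons overlap a gene on the opposite strand.

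Among the lists, at least 2-fold higher were 12 of 21, 14 of 20 and 16 of 24 sarcomere genes at days 2, 3 and 7, with medians of 1.28, 1.96 and 1.75, each at percentile 100. Only Tpm1, at day 7, was lower. Calcium handling genes were higher in 2 of 11, 4 of 9 and 5 of 9, among them the ryanodine receptor Ryr2 at days 3 and 7. Interferon response genes were higher in 6 of 21, 12 of 20 and 13 of 19, with medians of 0.84, 1.12 and 1.49. Macrophage markers were higher in 6, 3 and 10 of 12 at the same times, and without macrophage-like cells the interferon counts were 6, 12 and 14. G2M phase genes were higher in 25 of 52, 14 of 52 and 8 of 51. In the TGF-beta response list 11 of 22 were lower at day 7, Acta2 and Tagln among them, while 6 of 18 fibroblast identity genes were higher (Pdgfra, Thy1, Ddr2, S100a4, Prrx1, Ly6a). The extracellular matrix list had 5 members higher and 8 lower of 29 at day 7.

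**Figure D1:**
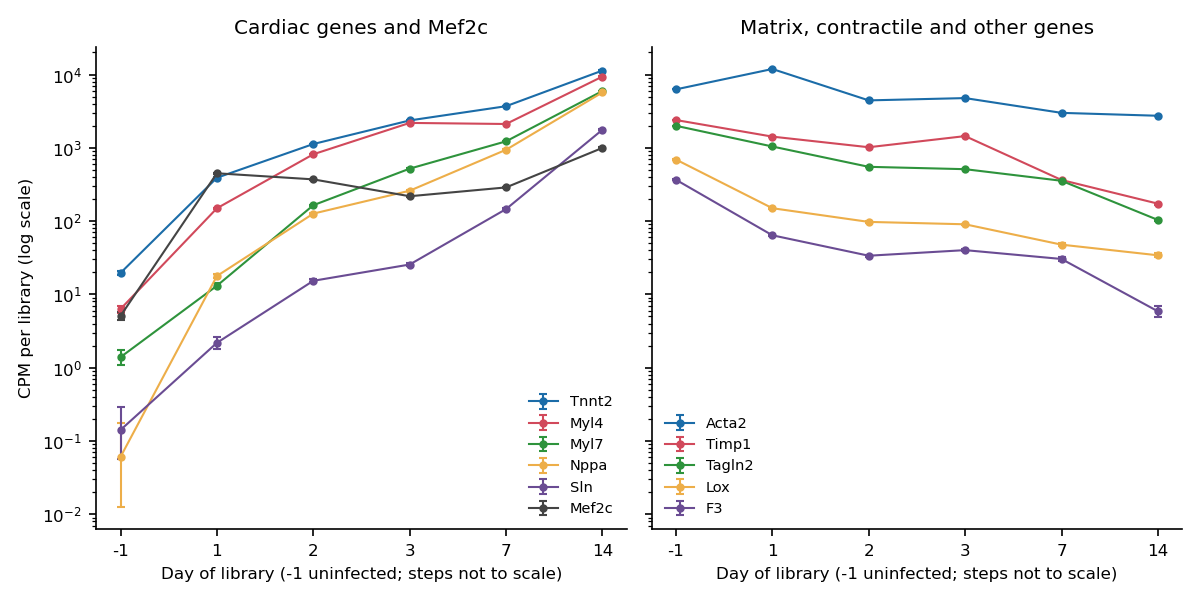
Levels of selected genes in the 6 libraries of the time course, in CPM on a log axis against day, with 1 library per point and bars for the exact 95% Poisson interval. Tnnt2, Myl4, Myl7, Nppa, Sln and Mef2c lay higher at day 14 than at day -1, and Acta2, Timp1, Tagln2, Lox and F3 lower.

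At day 14 cardiac contractile transcripts headed the differences, and most extracellular matrix genes were lower than in uninfected cells. Tnnt2 stood at 11339.5 CPM (11298 to 11381), 579-fold (543 to 617) above day -1, Myl4 at 9389 CPM (1488-fold, 1332 to 1668) and Myl7 at 5963 CPM (4288-fold, 3388 to 5511). Nppa (ENSMUSG00000041616, chromosome 4, 148000722 to 148002079) stood at 5702 CPM (5672 to 5732), and its ratio to the 3 UMIs at day -1 was 94294 (32265 to 457248). Actc1 (1782 CPM against 4 UMIs), the calcium pump regulator Sln (1767 CPM against 7 UMIs), the muscle LIM protein Csrp3 (1463 CPM against 5 UMIs) and the secretory granule protein Scg2 (1225 against 0.907 CPM) completed the 8 largest. Of 12320 genes compared, 892 were at least 2-fold higher and 720 at least 2-fold lower, and 861 and 985 when scaled without mitochondrially encoded and ribosomal protein genes.

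The smallest differences at day 14 included F3 (62.4-fold lower, 53.1 to 74.0), the actin bundler Fscn1 (40.5-fold, 36.2 to 45.5), Crct1 (34.7-fold), Lce1g (407-fold, 238 to 765), Tagln2 (19.3-fold), Lox (20.3-fold) and Timp1 (13.9-fold). Timp1, an inhibitor of matrix metalloproteinases (ENSMUSG00000001131, chromosome X, 20870166 to 20874735), stood at 173 CPM (168 to 178) against 2395 (2382 to 2409). Acta2 and Tagln, higher at day 1 though short of 2-fold, were 2.29-fold and 2.17-fold lower at day 14.

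Of 24 measured sarcomere genes 22 were at least 2-fold higher at day 14 and none lower, with a median of 3.19 (percentile 100). Of the 19 calcium handling genes 10 were measured and 6 were higher (median 1.92). These included Atp2a2 (777 against 104 CPM, 7.48-fold), Trdn, the triadin of the calcium release complex (163 CPM against 7 UMIs), Ryr2, Casq2 and Pln. Of the transcription factor and natriuretic peptide list 2 of 8 were higher, Nppa and Nppb (509 against 6.75 CPM, 75.4-fold), and Ankrd1 stood at 4524 against 2553 CPM. Of the 10 atrial genes 8 were measured and 5 were higher (median 5.38). Of the 8 ventricular genes only 3 were measured, and 2 of these were higher. They were Lbh (2.94-fold) and Myh7, whose ratio to 1 UMI at day -1 was 1490.2 (267 to 58938). Myl1, an embryonic and skeletal muscle light chain, stood at 236 CPM with 0 UMIs at day -1, at least 3908-fold higher, and 3 of 4 skeletal muscle genes were higher. Mitochondrial energy genes were higher in 10 of 23 (median 0.88), with the respiratory chain subunit Ndufa4 3.17-fold higher, and 2 of 17 glycolysis genes were lower, Ldha (2.96-fold) and Tpi1.

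Extracellular matrix genes were lower in 22 of 29 and higher in 1, the collagen processing enhancer Pcolce, with a median of -1.60 at percentile 0, although Sparc stood at 3898 against 2637 CPM. TGF-beta response genes were lower in 11 of 22 and higher in 1, Myl9 (median -0.96). Fibroblast identity genes were higher in 2 of 17 (S100a4 6.17-fold, Ly6a) and lower in 2 (Pdgfrb, Osr1), and Vim stood at 2151 against 3141 CPM. Of 6 Wnt targets Ccnd1 was higher (4.96-fold) and Nkd2 lower (14.0-fold). G2M phase genes were higher in 1 of 44, Cenpa (62.4-fold), and S phase genes lower in 2 of 41. All 3 reprogramming factors were at least 2-fold higher.

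Interferon response genes were higher in 9 of 17 at day 14 (median 1.07), including Isg15, a ubiquitin-like protein (243 against 15.6 CPM, 15.6-fold), and Ifi27l2a (17.2-fold). Inflammatory genes were lower in 6 of 16, with the macrophage growth factor Csf1 8.35-fold lower, and higher in 2, Ccl7 (612 against 98.3 CPM) and Ccl8. The p53 list had 6 of 12 higher and the immediate early list 2 of 13, Fos and Dusp1, with the heat-shock gene Hspa1a lower. The integrated stress response list had Vldlr higher, and Atf4 (4.58-fold) and Ddit4 lower. Markers of other types were 6 of 12 macrophage genes higher (Lyz2, a lysozyme, 2.21-fold; Fcer1g 5.56-fold), 3 of 9 epicardial genes higher (Upk1b 14.9-fold, Msln 31.2-fold, Upk3b), Flt1 lower of 3 endothelial genes (4.29-fold), Mcam higher and Ndufa4l2 and Lmod1 lower of 6 pericyte genes, Cebpa lower of 6 adipocyte genes and the secreted phosphoprotein Spp1 higher (12.4-fold) of 4 bone genes. The macrophage marker Ctss was 3.15-fold higher, a difference that was absent without macrophage-like, endothelial-like and Schwann-like cells (log2 -0.0086). Exons of Myl4, Nppa, Myh7, Atp2a2, Tagln, Lox and Ccnd1 overlap a gene on the opposite strand, and those of S100a4 and Spp1 on the same strand.

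**Figure D2:**
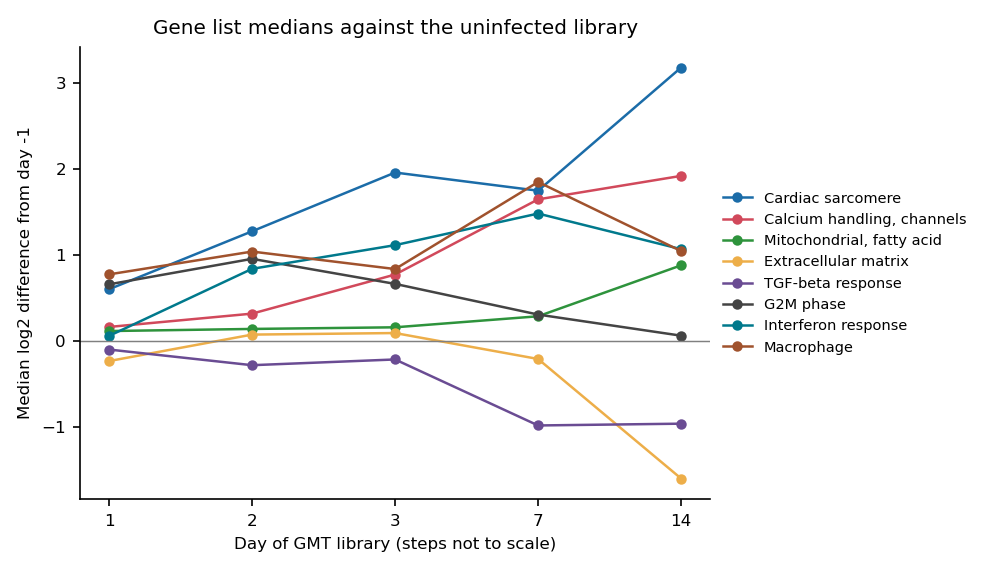
Median log2 difference from day -1 of 8 gene lists at each GMT time, with 1 library per time. The sarcomere median lay at 0.61 at day 1 and 3.19 at day 14, and the extracellular matrix median at -0.23 and -1.60.

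Between consecutive times the steps differed in size. From day 1 to day 2, 68 genes were at least 2-fold higher and 24 lower of 13468. The largest were Myl7 (165 against 13.1 CPM, 12.6-fold), Isg15 (174 against 24.9), Myl4 (817 against 149.5), Nppa (126 against 17.8) and the extracellular peroxidase Gpx3 (589 against 133). The smallest were the glutamate transporter Slc1a6 (4.97-fold lower), Crct1 (3.95-fold), Chchd10 (2.99-fold), Acta2 (4440.0 against 11906 CPM, 2.68-fold) and the myelin protein Pmp22 (2.77-fold). The higher share of this step was 73.9%, and 47.1% with median-of-ratios scaling. From day 2 to day 3, 16 of 13952 genes were higher and 0 lower, led by Myl7 (3.16-fold), the serpin Serpina3n (3.98-fold), Myl4 (2.68-fold), the muscle phosphoglycerate mutase Pgam2 (3.04-fold) and Ctla2a (2.72-fold), and the smallest, short of the 2-fold rule, were Map3k7cl (log2 -0.9969), Esm1 (-0.99), Sms (-0.91), Pclaf (-0.90) and Npnt (-0.83).

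From day 3 to day 7, 103 genes were at least 2-fold higher and 24 lower of 13370, and 75 and 44 with median-of-ratios scaling. The largest were Scg2 (249 against 17.5 CPM), the stromelysin Mmp3 (455 against 55.3), Igfbp5 (220.5 against 24.9), Wfdc17 (533 against 87.7) and the calcium buffer Pvalb (47.3 against 1.51). The smallest were the matrix protein Fbln2 (4.53-fold lower), Timp1 (3.97-fold), the translation factor Eef1b2 (2.63-fold), Siglecg (3.29-fold) and S100a3 (4.66-fold). From day 7 to day 14, where the "pos" label also differs, 242 genes were higher and 300 lower of 12429. The largest were Tnnc1, cardiac troponin C (1324 against 80.6 CPM, 16.4-fold), Sln (12.1-fold), the glutathione transferase Gsta1 (13.9-fold), Nppb (9.53-fold) and the ATP synthase subunit Atp5l (8.42-fold). The smallest were Mmp3 (8.59-fold lower), Col8a1 (8.40-fold), the noncoding RNA Meg3 (8.84-fold), the hyaluronan-binding Cemip (7.01-fold) and Prkar2b (11.7-fold). In this step 19 of 24 sarcomere genes were higher (median 1.67), 19 of 29 extracellular matrix genes were lower (median -1.25), and 9 of 18 fibroblast identity genes were lower, with none of the last 2 lists higher.

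Shares of cells with cardiac transcripts were read after thinning to 3000 UMIs. Tnnt2 was detected in 4.04% of cells at day -1 (3.45 to 4.69), 31.0% at day 1 (29.5 to 32.5), 54.0% at day 2, 59.5% at day 3 (58.4 to 60.6), 73.5% at day 7 (72.2 to 74.8) and 93.5% at day 14 (92.4 to 94.4). In macrophage-like cells, which should lack it, the Tnnt2 share was 0.662, 7.87, 18.1, 29.2, 48.0 and 36.9% in the same order, at the median depths given above for Mef2c. Unthinned Tnnt2 shares were 10.9, 48.4, 73.9, 77.1, 92.8 and 97.2%. At day 14 Myl4 was detected in 88.6% of all cells and 30.6% of macrophage-like cells, Myl7 in 72.9 and 26.1%, Nppa in 57.4 and 23.4%, and Actc1 in 45.5 and 17.1%.

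Ryr2, the calcium release channel of the sarcoplasmic reticulum, was detected in few macrophage-like cells. Its thinned share was 0 of 3990 cells at day -1 (up to 0.0752%), 0.110% at day 1, 2.76% at day 2, 3.27% at day 3, 9.41% at day 7 and 27.1% at day 14, against 0, 0, 0, 0.704, 0.420 and 2.70% of macrophage-like cells. Myh6, the alpha-myosin heavy chain whose promoter drives the reporter, was detected in 2.91% of cells at day 7 and 18.5% at day 14, against 0.559 and 1.802% of macrophage-like cells. Pln, phospholamban, was detected in 0.675 and 2.87%, against 0% and 0%. Those zeros allow shares of up to 0.420 and 2.70%, so Pln hardly tells the cells apart at day 14. Unthinned shares at day 14 were 54.7% for Ryr2, 30.3% for Myh6, 4.82% for Pln, 94.6% for Myl4, 84.6% for Myl7, 74.4% for Nppa and 57.4% for Actc1.

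**Figure D3:**
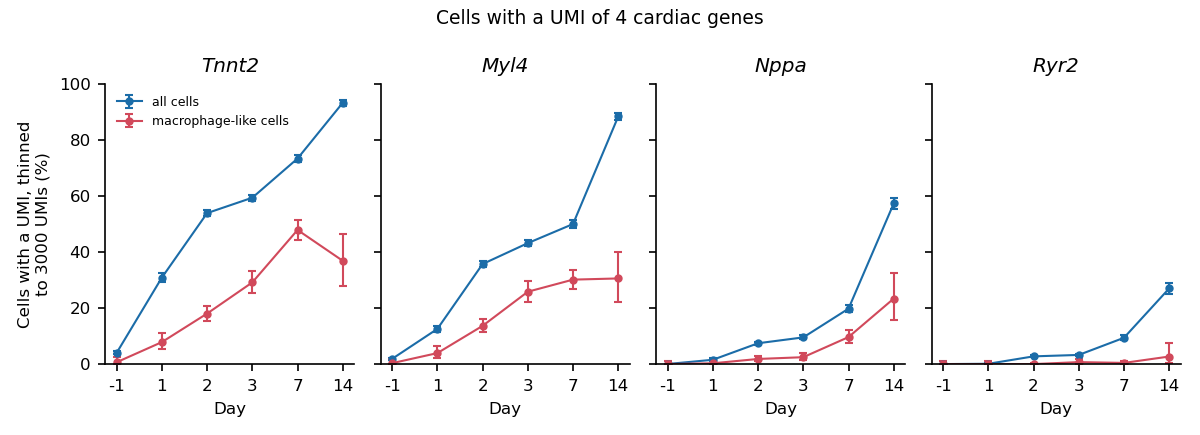
Share of cells, in percent, with at least 1 UMI of Tnnt2, Myl4, Nppa and Ryr2 after thinning to 3000 UMIs, by day, for all cells and for macrophage-like cells, with exact 95% binomial bars. Tnnt2 at day 7 was detected in 73.5% of all cells and 48.0% of macrophage-like cells, and Ryr2 in 9.41 and 0.420%.

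Joint clustering of the 30729 cells of the time course gave 23 clusters. Induced cardiomyocyte-like cells made up 0 of 4098 cells at day -1 (up to 0.0732%), 0.0275% at day 1 (0.0007 to 0.153), 0.0222% at day 2, 1.03% at day 3 (0.814 to 1.29), 25.6% at day 7 (24.3 to 27.0) and 84.98% at day 14 (83.5 to 86.4). Clustering without any cell type marker among the variable genes, chosen after the data were seen, gave 1.07% at day 3, 25.8% at day 7 and 85.2% at day 14. With 15 in place of 30 principal components the class held 4.56% at day 2 and 8.05% at day 3. At day 7 it held 30.8% at Leiden resolution 0.4 and 18.0% at resolution 1.2. An unnamed cluster led by Nid2 and Map3k7cl, with 5 markers of the class 2-fold above other cells but none among its 10 leading genes, held 27.4% of cells at day 2, 20.1% at day 3 and 2.19% at day 7. The naming thresholds were set after the clusters were seen, the genes behind these clusters differ between libraries, and the day 14 share also carries the "pos" label.

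Macrophage-like cells made up 7.52% of cells at day -1 (6.73 to 8.37), 9.80% at day 1, 9.08% at day 2, 7.72% at day 3, 16.7% at day 7 (15.5 to 17.8) and 4.82% at day 14 (3.98 to 5.77). At day -1 most of them lay in a macrophage-like cluster of their own. Proliferating-like cells, which at day -1 also lay mostly in a cluster of their own, made up 4.03% at day -1, 19.7% at day 1 (18.4 to 21.0), 22.9% at day 2 (22.1 to 23.8), 12.6% at day 3, 2.89% at day 7 and 0.732% at day 14 (0.427 to 1.17). An unnamed cluster with 9 proliferation markers raised, led by Pmaip1 and Gdf15, held between 0.0244 and 1.09% of each library. Epicardial or mesothelial-like cells made up 2.196% at day -1 and 1.72% at day 14, endothelial-like cells 1.02 and 0.0861%, Schwann-like cells 0.464 and 0.0430% (1.47% at day 7), and myofibroblast or smooth muscle-like cells 0.342 and 1.25% (6.44% at day 1). Unnamed clusters held 84.4, 61.1, 59.8, 68.8, 12.1 and 3.01% of cells along the time course, and 99.7% of the largest day -1 cluster came from that library. The fibroblast-like share was therefore not compared for times before day 7. The day -1 share of myofibroblast or smooth muscle-like cells may be too low for the same reason. Fibroblast-like cells made up 36.4% of cells at day 7 and 3.36% at day 14. The step from day 7 to day 14 therefore also compares libraries with different shares of this class.

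**Figure D4:**
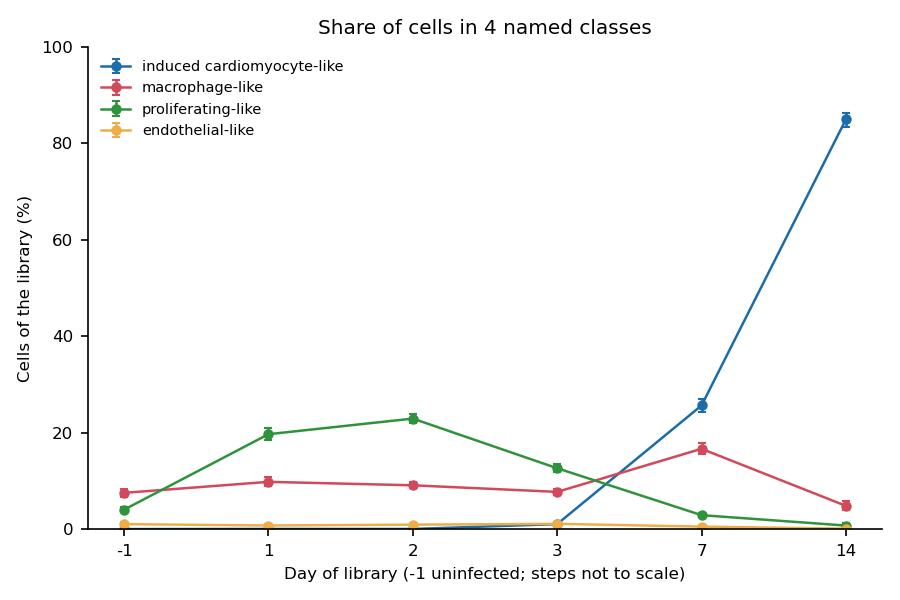
Share of cells, in percent of each library, in 4 classes named from markers fixed beforehand, by day, with exact 95% binomial bars and 1 library per time. Induced cardiomyocyte-like cells lay at 25.6% at day 7 and 84.98% at day 14, and proliferating-like cells at 22.9% at day 2 and 0.732% at day 14.

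Phase scores from the S and G2M lists called 24.0% of thinned cells in S or G2M at day -1 (22.6 to 25.3), 44.3% at day 1 (42.6 to 45.9), 41.6% at day 2 (40.6 to 42.6), 29.0% at day 3, 17.8% at day 7 and 13.2% at day 14 (11.8 to 14.6). Unthinned calls gave 14.2, 35.7, 35.6, 22.7, 11.3 and 3.79%. A threshold of 0.1 gave 6.79, 23.4, 26.7, 16.4, 7.73 and 1.99%, which turned the order of days -1 and 7 and of days 1 and 2. Calls of G2M alone covered 0.777% of thinned cells at day -1, 14.9% at day 1, 17.9% at day 2, 11.9% at day 3, 4.91% at day 7 and 1.32% at day 14. Between 36.6 and 48.8% of cells lay within 0.05 of a threshold, and free RNA was not removed from the scores.

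The day 1 5p library, deposited in its own table, was set beside the day 1 library of the time course. Gata4 stood at 238 CPM (234 to 242) in the 5p library against 24.6, Tbx5 at 71.7 (69.4 to 74.1) against 5.08 and Mef2c at 152 (148 to 155) against 449. Tnnt2 was detected in 24.2% of thinned 5p cells (22.6 to 25.8) against 31.0%, and Myl4 in 5.14 against 12.6%. Across the 12985 genes with at least 100 UMIs, log2(CPM + 10) correlated with a Pearson coefficient of 0.930 and a Spearman coefficient of 0.893, though genes are not independent replicates. Of these genes 646 were at least 2-fold higher in the 5p library and 260 lower, 6.98% together. With 1 CPM added these were 1799 and 648 (18.8%), and among genes with at least 1000 UMIs 11.2% differed, with a Spearman coefficient of 0.819. Pseudogenes took 3.40% of its UMIs against 1.08%. No 5p library of uninfected cells was analysed here, so no difference from day -1 was drawn from it.

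Within each GMT library, cells with a UMI of Gata4, Mef2c or Tbx5 were set against cells with none, all thinned to 3000 UMIs. The ratios use counts summed over a list, so abundant genes weigh most and a ratio does not stand for every member. In the transcription factor and natriuretic peptide list these include Ankrd1 and, at day 14, Nppa. In the fibroblast identity list they include Vim. Sarcomere transcripts were higher in cells with a factor UMI in 5 of 5 libraries, with log2 ratios of 0.84 at day 1 (0.812 to 0.860), 1.23 at day 2 (1.22 to 1.24), 1.504 at day 3 (1.49 to 1.52), 1.83 at day 7 (1.81 to 1.84) and 0.78 at day 14 (0.767 to 0.799). Calcium handling transcripts were higher in 5 of 5, from 0.35 at day 1 to 2.07 at day 7. Transcription factor and natriuretic peptide transcripts were higher in 5 of 5, by 0.029 at day 14 and at most 0.91 at day 7, and the day 14 value turned negative without macrophage-like, endothelial-like and Schwann-like cells (-0.27). Extracellular matrix transcripts were lower in 4 of 5 libraries, down to -0.25 at day 14, and higher by 0.029 at day 1, which also turned (-0.13) without those cells. Without thinning they were lower in 2 of 5 libraries, and higher at day 2 (0.063) and day 7 (0.082). Fibroblast identity transcripts were higher in 5 of 5, from 0.71 at day 1 to 0.0037 at day 7, where the interval of -0.0207 to 0.0280 spans 0. This list was lower at day 7 without macrophage-like, endothelial-like and Schwann-like cells (-0.077), and at days 7 and 14 without thinning (-0.017 and -0.12).

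The 5p library gave a sarcomere ratio of 0.69 (0.661 to 0.715) and an extracellular matrix ratio of 0.14 (0.129 to 0.160). Cells without a factor UMI also held sarcomere transcripts, at 3951 CPM at day 1 and 25542 CPM at day 14, against 7052 and 43950.2 CPM in cells with one. The list includes Tpm1, which stood at a high level in uninfected cells too, so part of these sums needs no virus. Free RNA was not removed from them either. A cell without a factor UMI may still carry the virus, because thinned depth leaves low transcripts unread. Depth need not be the only reason. At the same 3000 UMIs, Gata4 was detected in 34.2% of 5p cells against 7.19% at day 1. Tbx5 was detected in 14.97 against 1.35%, and Mef2c, the other way, in 23.9 against 38.1%. A Gata4 UMI need not be viral, since Gata4 was detected in 8.45% of uninfected cells. No such split of uninfected cells is reported here as a baseline.

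**Figure D5:**
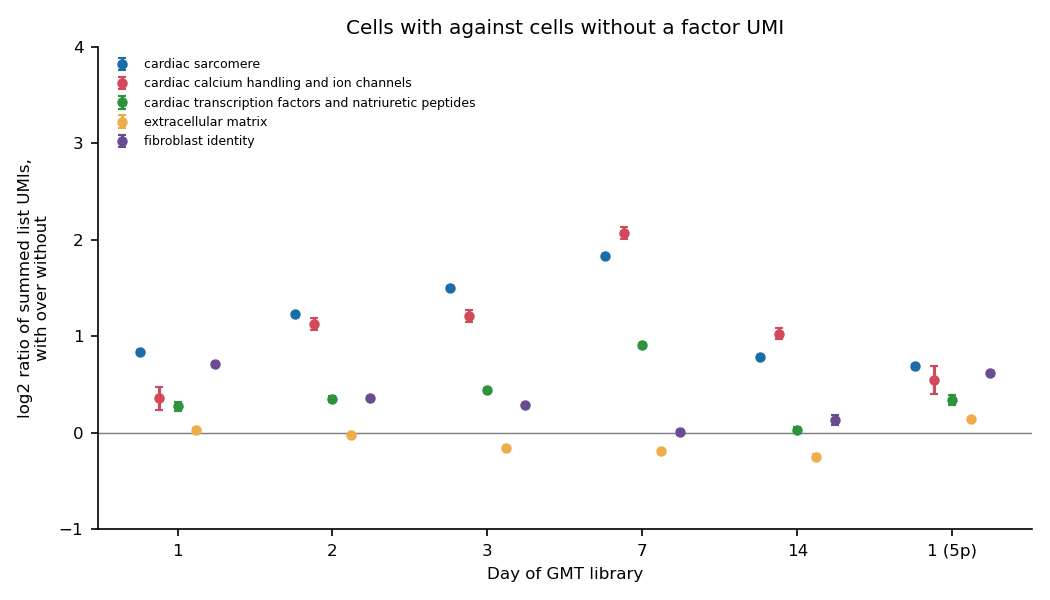
Log2 ratio of summed counts in cells with over cells without a UMI of Gata4, Mef2c or Tbx5, for 5 gene lists in 6 GMT libraries, after thinning to 3000 UMIs, with 95% counting intervals. Sarcomere ratios lay between 0.69 and 1.83, and extracellular matrix ratios between -0.25 and 0.14.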

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

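The exclusion of macrophage-like, endothelial-like and Schwann-like cells, that of the 5% of cells with the highest doublet scores, and clustering without cell type markers were chosen only after the results were seen. The other alternatives were fixed before the data were examined. No paired analysis was possible because every group has a single library, all numbered replicate 1, and no result here comes from a test. Of the values behind the main comparisons, 290 stayed within their tolerance and 112 did not. A count was tolerated within 1.5 times of its main value, a share within its exact binomial interval and a CPM within its Poisson interval.

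With 1 CPM added in place of 10, genes of low level passed the 2-fold rule more often. This gave 624 genes higher at day 1 than at day -1 (main 201), 665 genes lower at day 1 than at day -1 (main 154), 1337 genes higher at day 2 than at day -1 (main 402), 774 genes lower at day 2 than at day -1 (main 273), 1262 genes higher at day 3 than at day -1 (main 399), 1039 genes lower at day 3 than at day -1 (main 379), 1868 genes higher at day 7 than at day -1 (main 733), 1067 genes lower at day 7 than at day -1 (main 415), 1852 genes higher at day 14 than at day -1 (main 892), 1658 genes lower at day 14 than at day -1 (main 720), 368 genes higher at day 2 than at day 1 (main 68), 58 genes lower at day 2 than at day 1 (main 24), 44 genes higher at day 3 than at day 2 (main 16), 11 genes lower at day 3 than at day 2 (main 0), 345 genes higher at day 7 than at day 3 (main 103), 101 genes lower at day 7 than at day 3 (main 24), 631 genes higher at day 14 than at day 7 (main 242), 970 genes lower at day 14 than at day 7 (main 300). By list it gave 14 cardiac sarcomere genes at day 1 (main 8), 3 cardiac calcium handling and ion channels genes at day 1 (main 0), 37 G2M phase genes at day 1 (main 19), 5 G2M phase genes at day 14 (main 1). With genes of at least 1000 UMIs only, the lists gave 5 cardiac sarcomere genes at day 1 (main 8).

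Scaling mattered for the smaller steps. Median-of-ratios scaling gave 93 genes lower at day 1 than at day -1 (main 154), 40 genes higher at day 2 than at day 1 (main 68), 45 genes lower at day 2 than at day 1 (main 24), 44 genes lower at day 7 than at day 3 (main 24). Leaving mitochondrially encoded and ribosomal protein genes out of the total gave 2 genes lower at day 3 than at day 2 (main 0), 51 genes lower at day 7 than at day 3 (main 24). The mean of each cell's CPM gave 1 gene lower at day 3 than at day 2 (main 0), 48 genes lower at day 7 than at day 3 (main 24). Without called doublets there was 1 gene lower at day 3 than at day 2 (main 0). The cause was not tested.

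Factor levels depended on scaling too. Median-of-ratios scaling put Gata4 at 27.4 (main 24.6) at day 1, 46.5 (main 47.9) at day 2, 44.6 (main 43.0) at day 3, 53.3 (main 57.0) at day 7 CPM, and Mef2c at 500.5 (main 449) at day 1, 361 (main 371) at day 2, 226 (main 218) at day 3, 269.6 (main 288) at day 7, 967 (main 998) at day 14. The mean of each cell's CPM put Gata4 at 40.6 (main 43.0) at day 3, 245 (main 238) at day 1 5p, Mef2c at 6.56 (main 5.08) at day -1, 410.4 (main 371) at day 2, 243 (main 218) at day 3, 349 (main 288) at day 7, 1028 (main 998) at day 14, and Tbx5 at 7.01 (main 6.50) at day 2, 5.89 (main 5.38) at day 3, 6.82 (main 5.87) at day 7.

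The share of cells with Tnnt2 followed depth. In percent it was 10.9 (main 4.04) at day -1, 48.4 (main 31.0) at day 1, 73.9 (main 54.0) at day 2, 77.1 (main 59.5) at day 3, 92.8 (main 73.5) at day 7, 97.2 (main 93.5) at day 14 without thinning. Thinned to 1500 UMIs it was 2.46 (main 4.04) at day -1, 23.6 (main 31.0) at day 1, 45.0 (main 54.0) at day 2, 50.2 (main 59.5) at day 3, 63.4 (main 73.5) at day 7, 91.7 (main 93.5) at day 14. With at least 2 UMIs asked it was 1.05 (main 4.04) at day -1, 20.2 (main 31.0) at day 1, 40.4 (main 54.0) at day 2, 46.3 (main 59.5) at day 3, 57.5 (main 73.5) at day 7, 90.6 (main 93.5) at day 14.

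The induced cardiomyocyte-like share, in percent, was 0.303 (main 0.0275) at day 1, 4.56 (main 0.0222) at day 2, 8.05 (main 1.03) at day 3 with 15 principal components, 0.155 (main 0.0222) at day 2, 3.26 (main 1.03) at day 3, 30.8 (main 25.6) at day 7 at Leiden resolution 0.4, and 0.774 (main 1.03) at day 3, 18.0 (main 25.6) at day 7, 81.4 (main 84.98) at day 14 at resolution 1.2. The shares up to day 7 therefore rest on the clustering settings. Phase calls, in percent in S or G2M, were 14.2 (main 24.0) at day -1, 35.7 (main 44.3) at day 1, 35.6 (main 41.6) at day 2, 22.7 (main 29.0) at day 3, 11.3 (main 17.8) at day 7, 3.79 (main 13.2) at day 14 without thinning, and 6.79 (main 24.0) at day -1, 23.4 (main 44.3) at day 1, 26.7 (main 41.6) at day 2, 16.4 (main 29.0) at day 3, 7.73 (main 17.8) at day 7, 1.99 (main 13.2) at day 14 with a score threshold of 0.1.

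In cells with against without a factor UMI, log2 ratios with a UMI of Mef2c alone were sarcomere 0.90 (main 0.84) at day 1, 1.31 (main 1.23) at day 2, 1.62 (main 1.504) at day 3, 1.88 (main 1.83) at day 7, 0.77 (main 0.69) at day 1 5p, extracellular matrix -0.0078 (main 0.029) at day 1, cardiac transcription factor -0.097 (main 0.029) at day 14. Without thinning they were sarcomere 0.64 (main 0.84) at day 1, 1.31 (main 1.23) at day 2, 1.47 (main 1.504) at day 3, 1.75 (main 1.83) at day 7, 1.33 (main 0.78) at day 14, 0.61 (main 0.69) at day 1 5p, extracellular matrix 0.063 (main -0.025) at day 2, 0.082 (main -0.19) at day 7, fibroblast identity -0.12 (main 0.13) at day 14. With at least 2 factor UMIs they were sarcomere 0.93 (main 0.84) at day 1, 1.201 (main 1.23) at day 2, 1.86 (main 1.83) at day 7, 0.53 (main 0.78) at day 14, 0.77 (main 0.69) at day 1 5p, cardiac transcription factor -0.17 (main 0.029) at day 14. Sarcomere and calcium handling ratios were positive in every setting, and the other 3 lists each took both signs in some setting.

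Without macrophage-like, endothelial-like and Schwann-like cells those ratios were sarcomere 0.69 (main 0.84) at day 1, 1.07 (main 1.23) at day 2, 1.41 (main 1.504) at day 3, 1.58 (main 1.83) at day 7, 0.49 (main 0.78) at day 14, extracellular matrix -0.13 (main 0.029) at day 1, cardiac transcription factor -0.27 (main 0.029) at day 14. The same exclusion gave 2 genes lower at day 3 than at day 2 (main 0), and Ctss at day 14 over day -1 at a log2 difference of -0.0086 (main 1.53).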

Other observations

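The comparison of induced cardiomyocyte-like cells between days, the test of free RNA for Atp5l, and the ribosomal shares without cluster 15 and in induced cardiomyocyte-like cells were chosen only after the results were seen. Within the induced cardiomyocyte-like class, day 14 cells were set against day 7 cells, and 78 of 10371 genes were at least 2-fold higher and 57 lower. Sarcomere genes were higher in 4 of 24 (median 0.50): Tnnc1, cardiac troponin C, stood at 1567 against 307 CPM (log2 2.31), Csrp3, a Z-disc LIM protein, at 1737 against 711, the skeletal actin Acta1 at 125 against 19.6 and the slow myosin heavy chain Myh7 at 35.9 against 9.10. Calcium handling genes were higher in 1 of 10, Sln, with a median of -0.052.

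In the same cells extracellular matrix genes were lower in 8 of 27 (median -0.81), with the fibrillar collagen Col3a1 at a log2 difference of -1.82, fibronectin Fn1 at -1.55 and Col1a1 at -1.19. Fibroblast identity genes were lower in 4 of 14 (median -0.41). The mesothelial genes Upk1b (130.0 against 44.9 CPM) and Msln (50.2 against 13.5) were higher. The macrophage genes Lyz2 and Tyrobp were lower, at 52.0 against 132 CPM and 2.60 against 15.7 CPM. The class joins 2 clusters, and the smaller held 105 cells at day 14 and 2 at day 7, so the cells compared are partly of different clusters. The day 14 library carries the "pos" label, and free RNA differs between the libraries.

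Ribosomal protein genes took 22.5% of UMIs at day 3, 14.4% at day 7 and 12.4% at day 14. Reads could have moved to pseudogenes, but the pseudogene share at day 7 differed from day 3 by -0.149 percentage points, against that explanation. A different mix of cell types could lower the share, yet within macrophage-like cells the day 7 share was 0.744 of that at day 3 and within cells of no named class 0.704, both under the bound set beforehand. The clusters inside both sets differed between the days. In macrophage-like cells without cluster 15, nearly all of a single cluster at both days, the share was 15.5% at day 3 and 12.7% at day 7. In induced cardiomyocyte-like cells it was 21.1% (76 cells) and 14.1%. For that step, these values argue against a changed mix of the cells themselves as the whole cause. Free RNA was not removed, so they cannot exclude that a changed mix acted through RNA in these droplets. In the macrophage-like cells without cluster 15, the share was no higher at day 1 (12.6%) or day -1 (9.87%, mostly another cluster) than at day 7. That set therefore shows no fall from those days. Culture time, handling and translation itself were not tested.

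Interferon response genes were higher in 12 of 20 at day 3 and 13 of 19 at day 7. Macrophage-like cells were most frequent at day 7, and their RNA could carry such transcripts. Without macrophage-like cells 14 of 19 were higher at day 7 (median 1.53), against those cells themselves as the source. Free RNA was not removed, so this cannot exclude macrophage RNA in the droplets of other cells. Retroviral infection may also induce these genes, and no infected control without GMT was analysed here.

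Atp5l, a subunit of ATP synthase, stood at 771 CPM at day 14 against 91.6 at day 7. A library-wide difference in how reads were assigned could be behind it: in macrophage-like cells the log2 difference was 2.55, within the range that explanation named beforehand, although a biological difference of the whole library stays open. A larger share of induced cardiomyocyte-like cells at day 14 is unlikely to account for it alone, since within that class the difference was 2.73. Free RNA from that class is unlikely too, because the ratio of macrophage-like to induced cardiomyocyte-like level at day 14 was 17.6 times that of Tnnt2.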
